A study of Homo sapiens with 6 samples.

How the data were processed

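RNA from 6 samples of SW480 cells, 3 labelled as CPEB3-overexpressing and 3 as negative control, was hybridised to Affymetrix HG-U133 Plus 2.0 arrays by the authors. The deposited values are 1 normalized intensity per probe set and array on a linear scale. Per the submitters' processing notes they were made with RMA, and the tool version, the probe set definition and the step that brought RMA's log2 values to a linear scale are not given in the sources used here. All values were above 0, and array medians lay between 14.8 and 15.2. RMA sets the distribution of every array to be alike, so a change of total RNA per cell is not measured, and it compresses differences of dim probe sets. The tests had been planned for log2 values, so log2 was taken of the deposited intensity before any test, as the plan provided.

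Groups and replicate numbers were taken from the sample titles. Arrays have no depth, and their number limits the precision. No detection calls were used, so whether a dim probe set lies above background was not tested, and folds of dim genes can be understated. Of the 54675 probe sets, 62 are control probe sets, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 are unnamed here. Probe sets with several symbols were not used for named genes. Each of the 19777 genes was represented by its single-gene probe set with the highest mean over all 6 arrays. Symbols were compared through Entrez identifiers with a RefSeq gene table (GRCh38.p14), which held 19735 of the genes, and 0 were updated. No genome build is stated for the values, so no coordinates are given. List members without a single-gene probe set were not analysed here.

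Differences are arrays labelled CPEB3 minus arrays labelled NC. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 4 residual degrees of freedom were joined by 5.06 prior degrees of freedom. The 26 gene lists were tested with camera (preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Under the estimated correlation the lists for interferon, immediate early genes, hypoxia and glycolysis, RAS-MAPK output, NF-kB, the unfolded protein and integrated stress response and IL6-JAK-STAT3 kept their calls. Lists share genes, and 1 member of the NF-kB list is also in the interferon list.

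The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named CPEB3, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members past the threshold with the largest change per list, and IL6R, IL6ST, STAT3, EGFR, CDH1, VIM, CDH2, SNAI1 and the CPEB family whatever their result. IFNB1, IFNL1 and the genes of the closing observations that fall outside the rule were chosen after their values were seen.

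The alternatives were the mean of all probe sets of a gene, the probe set with the largest variance, every probe set on its own, no probe sets that can match several transcripts, no dim genes, median centring, quantile normalization once more, an intensity trend, robust variances, array weights, the replicate number as a block, a threshold of 0.01, camera with an estimated correlation or on ranks, fry, and leaving out each array in turn. Spike-in centring and leaving interferon genes out of the other lists were added after the data were seen. The steps were tested on simulated data with the spread of these arrays for the comparison of 19777 genes. There the test recovered 4% of changes of 0.25 on the log2 scale, 74% of 0.5, 98% of 1 and 100% of 2. It made 4 false calls among 142, and camera called the shifted list and 0 of 25 lists without a shift. Fewer genes were changed there than in the real data (142 calls against 4616), so the adjusted threshold was stricter. The recovered shares therefore do not carry over to the real data, where 1119 called genes were under 1.2-fold. Simulated genes were drawn independently, so the simulation does not test camera for lists whose members correlate. In the real data estimated correlations reached 0.161, and splits of the arrays that mix both groups gave up to 9 called lists. Those splits can still carry part of the group difference, so their lists do not count false calls. Figures were drawn with matplotlib 3.10.9.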

Results

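Gene expression was measured with whole-genome oligonucleotide arrays (Affymetrix HG-U133 Plus 2.0) in SW480 cells, an established human colorectal adenocarcinoma line with mutations that activate the RAS and Wnt pathways. The labels describe 3 biological replicates transfected to overexpress CPEB3, an RNA-binding protein that binds cytoplasmic polyadenylation elements in the 3' untranslated regions of mRNAs and regulates their translation, and 3 biological replicates of a negative control (NC). Each array gave 1 normalized intensity for each of 54675 probe sets, and 19777 genes were tested after log2 was taken. Across all probe sets, arrays of 1 group correlated with r from 0.997 to 0.998. For arrays of different groups r was 0.991 to 0.992, probe sets not being independent replicates. The number of arrays limits the precision of every value. The labels call the replicates biological but give no culture or day for any of them, so p-values measure the spread between these samples.

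CPEB3 mRNA was examined first, since it checks the labels, and it went against them. At the most variable of its 4 probe sets the log2 intensity was 2.31 ± 0.21 in the arrays labelled CPEB3 and 3.75 ± 0.21 in the arrays labelled NC (SD, n = 3 each), a difference of -1.44 (SE 0.12), or 2.72-fold lower where overexpression was labelled (limma, Benjamini-Hochberg adjusted p = 7.79e-05). Both levels lay below the median probe set of each array (3.89 to 3.93), so this fall rests on a dim probe set. Another pair of dim probe sets was also lower (2.95 against 3.30, and 1.74 against 1.99), with limma and Benjamini-Hochberg adjusted p = 0.00877 and 0.0473. The brightest probe set, which stands for the gene in the counts given here, was 5.37 ± 0.03 against 5.32 ± 0.07, a difference of 0.05 with a 95% interval from -0.09 to 0.18 (limma, Benjamini-Hochberg adjusted p = 0.616). The positions of the 4 probe sets relative to the coding sequence were not analysed here, and a probe set in the untranslated region does not see a construct that holds the coding sequence alone. The groups are therefore called the arrays labelled CPEB3 and the arrays labelled NC, and every direction given here rests on these labels. After each array was centred on its hybridization spike-ins, a choice made after the data were seen, the difference at the brightest probe set became 0.23 (limma, Benjamini-Hochberg adjusted p = 0.0432, against 0.391 to 0.935 under the other alternatives that use this probe set).

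**Figure D1:**
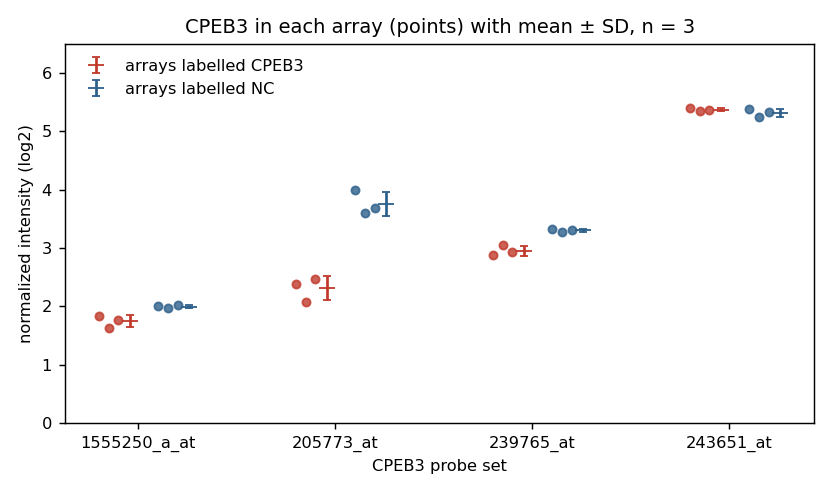
Normalized log2 intensity (vertical axis) of the 4 CPEB3 probe sets (horizontal axis) in the 3 arrays labelled CPEB3 (red) and the 3 labelled NC (blue). Points are arrays and bars show the mean ± SD. At the most variable probe set the means are 2.31 and 3.75, and at the brightest they are 5.37 and 5.32.

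The comparison of the groups asked how transcript levels differed in cells labelled as overexpressing CPEB3. The steepest differences were falls of interferon-stimulated genes, which cells switch on during antiviral responses. IFI44 was 3.51 ± 0.41 in the arrays labelled CPEB3 and 9.14 ± 0.07 in those labelled NC (SD, n = 3 each), a difference of -5.63 (SE 0.17), or 49.7-fold; without probe sets that can match several transcripts it was -3.65. SAMD9, an antiviral restriction factor, was 32.7-fold lower, IFI27 31.9-fold, IFIT3 24.0-fold and IFIT2 23.2-fold. IFNL2, which encodes a type III interferon, was 23.0-fold lower, although it has near-identical paralogs and its probe set can also read those. OAS1, the 2'-5' oligoadenylate synthetase that activates RNase L, fell by 4.39 on the log2 scale, IFITM1 was 17.7-fold lower, the immunoproteasome subunit PSMB9 15.9-fold, CMPK2 14.7-fold, IFIT1 12.9-fold and the cytosolic RNA sensor IFIH1 12.7-fold. In each of these 12 genes the 3 values of one group lay apart from the 3 of the other, and the largest of their limma Benjamini-Hochberg adjusted p-values was 6.08e-08.

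Rises were smaller. HINT3, a nucleoside phosphoramidase, rose by 2.44 on the log2 scale (SE 0.21, 5.41-fold) at 1 of its 3 probe sets, and by 0.78 with their mean. KRTAP3-1, a keratin-associated protein, rose 4.62-fold and the pseudogene WFDC21P 2.81-fold. The long noncoding RNA DANCR rose from 8.12 to 9.47 (2.56-fold), and IL18, a cytokine of the interleukin-1 family made by epithelial cells, from 6.77 ± 0.05 to 8.12 ± 0.15 (SD, n = 3 each, 2.56-fold). GALNT5, which starts O-linked glycosylation, rose 2.47-fold, with all 5 of its probe sets higher. The sulfatase activator SUMF1 rose 2.38-fold, the endoplasmic reticulum shaping GTPase ATL3 2.29-fold (1 of its 3 probe sets; log2 difference 1.19, or 0.47 with their mean), the carboxypeptidase CPA4 2.23-fold, the sodium pump regulator FXYD3 2.22-fold, FAM210B 2.12-fold and the p53 target ZMAT3 2.10-fold. The largest limma Benjamini-Hochberg adjusted p among these 12 was 9.75e-05.

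**Figure D2:**
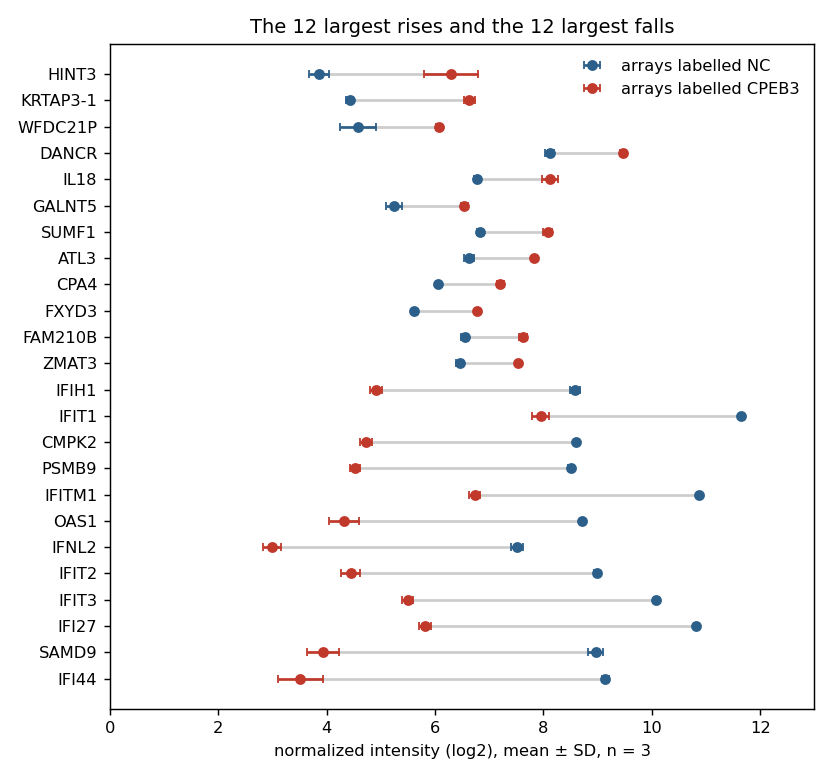
Mean normalized log2 intensity (horizontal axis, bars ± SD, n = 3) of the 12 genes with the largest rise and the 12 with the largest fall (vertical axis), in the arrays labelled CPEB3 (red) and NC (blue). The falls reach -5.63 for IFI44 and the rises 2.44 for HINT3.

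Over all genes, 4616 (23.3%) passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, of which 2146 were higher and 2470 lower in the arrays labelled CPEB3. Most of these changes were small, with a median absolute log2 difference of 0.34 and 1119 genes under 1.2-fold. At 2-fold or more, 191 genes had changed, 20 of them higher and 171 lower. The groups did not overlap in 7724 genes (39.1%), where chance gives 10%. The split between higher and lower depended on the scaling. The hybridization spike-ins were dimmer in the arrays labelled CPEB3 by 0.18 on the log2 scale on average. Their probe sets were uneven, with differences of -0.04 to -0.10 at the bright cre probe sets and up to -0.33 at a dimmer bioC one. Centring each array on their mean, a choice made after the data were seen, shifted all genes up by 0.18. It gave 7767 genes higher and 1038 lower, with 1 constant per array at every intensity.

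The interferon response list had 53 measured genes. Of these, 50 fell, 0 rose and 3 did not pass, or 52 fell adjusted over the list alone and 49 with spike-in centring. The median difference was -2.34 (camera, Benjamini-Hochberg adjusted p = 2.03e-60, adjusted p = 0.0334 with an estimated correlation), and 42 members fell at least 2-fold. The interferon gene IFNB1 was itself lower (-2.25), as was IFNL1 (-2.06). Leukocyte markers, as signs of another cell type, had a median difference of 0.07 beside this list, with 1 of 27 higher and 2 lower (the same adjusted over the list alone; 15 higher and 1 lower with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.279). ITGAM, the 1 that was higher, turned to -0.10 with the mean of its probe sets. Fibroblast and endothelial markers had 1 of 23 higher and 2 lower (the same adjusted over the list alone; 8 and 0 with spike-in centring), with a median of 0.04 and camera Benjamini-Hochberg adjusted p = 0.797.

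Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, fell in 27 of 32 measured members and rose in 0 (the same adjusted over the list alone; 26 and 0 with spike-in centring), with a median of -0.84 (camera, Benjamini-Hochberg adjusted p = 9.46e-25, adjusted p = 0.0242 with an estimated correlation). EGR3 was 5.79-fold lower, EGR1 4.76-fold, KLF4 3.98-fold and ATF3 3.87-fold. Of 36 genes induced by RAS-MAPK signalling, 25 fell and 2 rose (25 and 4 adjusted over the list alone; 17 and 5 with spike-in centring; median -0.40, or -0.22 so centred), with camera Benjamini-Hochberg adjusted p = 6.55e-12 and adjusted p = 0.0373 with an estimated correlation. JUN (2.36-fold) and FOS (2.85-fold) were among them. JUN, FOS, EGR1, EGR3, FOSB, FOSL1, IER2, IER3 and DUSP5 are also in the immediate early list, and all were lower. They include all 5 RAS-MAPK members that fell at least 2-fold, so these lists are not independent. Outside the overlap, LAMB3 (-0.92) and ELK3 (-0.71) fell, and the 2 that rose were CCND1 (0.28) and MYEOV (0.23). Among 35 NF-kB targets, 21 fell and 2 rose (23 and 2 adjusted over the list alone; 17 and 6 with spike-in centring; median -0.33, or -0.15 so centred), with camera Benjamini-Hochberg adjusted p = 5.54e-11 and adjusted p = 0.0373 with an estimated correlation. The neutrophil chemokine CXCL8 was 6.19-fold lower, CXCL1 3.24-fold, and TNFAIP3, an inhibitor of NF-kB signalling, 3.61-fold.

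Hypoxia and glycolysis genes fell in 34 of 42 measured members and rose in 2 (35 and 3 adjusted over the list alone; 26 and 4 with spike-in centring), with a median of -0.64, or -0.46 so centred (camera, Benjamini-Hochberg adjusted p = 1.20e-21, adjusted p = 0.0373 with an estimated correlation). The glucose transporter SLC2A3 was 7.48-fold lower (6.94 to 4.04), NDRG1 3.52-fold, the glycolytic regulator PFKFB4 3.45-fold and ANGPTL4 2.88-fold. Oxidative phosphorylation genes moved the other way, with 31 of 46 higher and 0 lower (35 and 0 adjusted over the list alone; 44 and 0 with spike-in centring; median 0.24, or 0.42 so centred). Their camera Benjamini-Hochberg adjusted p was 1.69e-12, a call lost with an estimated correlation (adjusted p = 0.0808 with an estimated correlation). ATP5MC1 rose by 0.52 and NDUFA1 by 0.47 on the log2 scale, and NDUFA2 by 0.81, the last 0.21 and not past the threshold without probe sets that can match several transcripts. Unfolded protein and integrated stress response genes fell in 25 of 44 members and rose in 7 (26 and 9 adjusted over the list alone; 20 and 13 with spike-in centring; median -0.36, or -0.18 so centred), with camera Benjamini-Hochberg adjusted p = 1.31e-07 and adjusted p = 0.038 with an estimated correlation. DDIT4, an inhibitor of mTORC1, was 3.83-fold lower, PPP1R15A, which lifts the translation block of that response, 2.87-fold, and the transcription factor DDIT3 2.58-fold. The 7 that rose were DNAJC3 (0.445), SDF2L1 (0.441), CALR (0.364), PDIA6 (0.328), HERPUD1 (0.282), CRELD2 (0.274) and SEL1L (0.223). HSPA5 (0.094) and HSP90B1 (0.004) did not pass, and XBP1 (-0.317) and PDIA4 (-0.359) fell. The fall therefore did not cover the whole list.

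**Figure D3:**
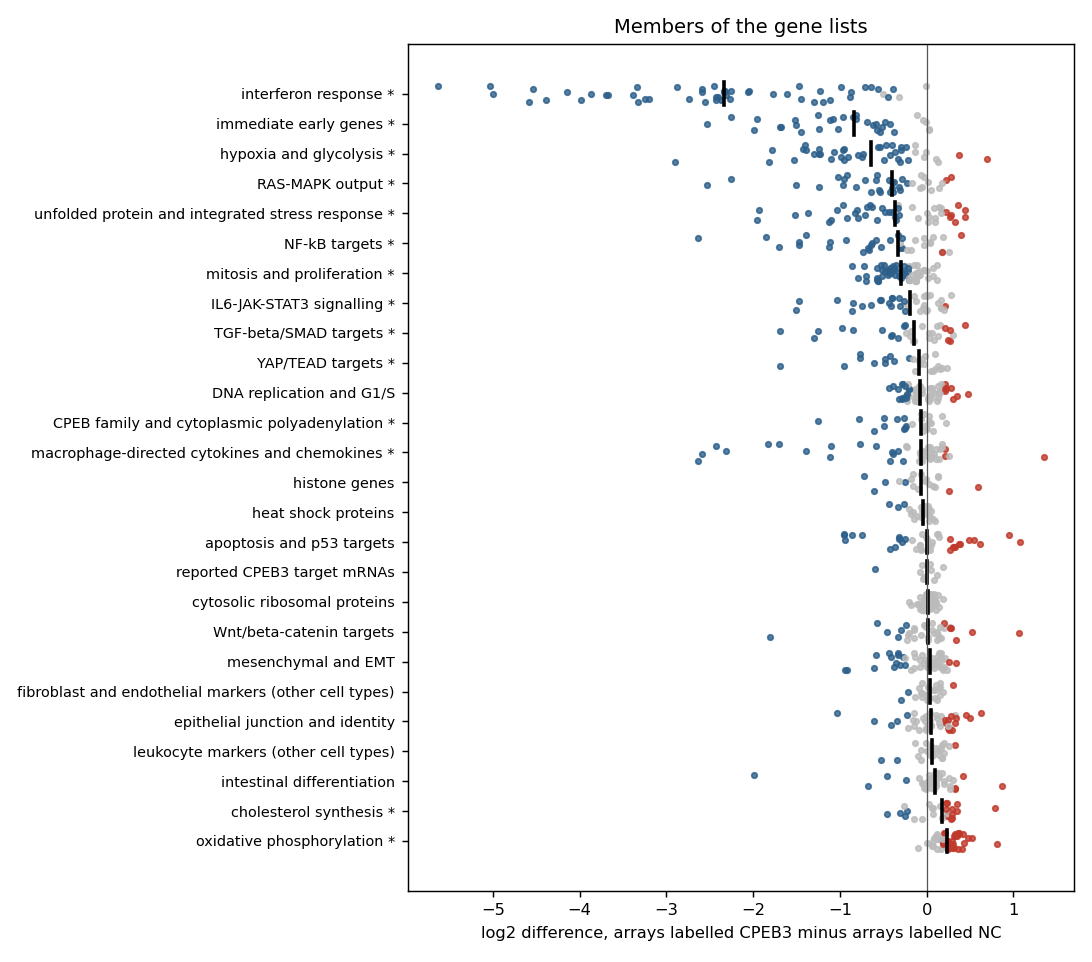
Log2 difference, arrays labelled CPEB3 minus arrays labelled NC (horizontal axis), of every measured member of the 26 gene lists (vertical axis). Points are genes (red higher and blue lower at adjusted p under 0.05, grey not past it), black lines are list medians, and asterisks mark lists called by camera. Interferon genes have a median of -2.34 and oxidative phosphorylation genes one of 0.24. Centring on the spike-ins moves all points right by 0.18.

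Genes of mitosis and proliferation fell in 37 of 61 members and rose in 0 (41 and 0 adjusted over the list alone; 21 and 4 with spike-in centring; median -0.29, or -0.12 so centred), each by less than 2-fold. Camera gave a Benjamini-Hochberg adjusted p = 8.36e-16, a call lost with an estimated correlation (adjusted p = 0.0516 with an estimated correlation). The mitotic kinase AURKB was 1.82-fold lower and the proliferation marker MKI67 1.73-fold. DNA replication and G1/S genes went both ways, with 8 of 58 higher and 14 lower (9 and 16 adjusted over the list alone; 19 and 1 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.173). Apoptosis and p53 target genes had 12 of 40 higher and 11 lower (12 and 12 adjusted over the list alone; 16 and 6 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.844), the median (0.00) and mean (-0.01) differing in sign. Among them TP53I3 rose 1.93-fold and GADD45B and BIK fell 1.93-fold each. Cytosolic ribosomal proteins had 0 of 52 members past limma's threshold (0 adjusted over the list alone, 4 at an unadjusted p under 0.05; camera, Benjamini-Hochberg adjusted p = 0.796) and 17 higher with spike-in centring. Heat shock proteins had 3 of 22 lower and 0 higher (the same adjusted over the list alone; 1 and 2 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.0937, or 0.0457 with the mean of probe sets and 0.0467 on ranks), and histone genes 2 of 19 higher and 4 lower (the same adjusted over the list alone; 6 and 3 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.238).

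Of 36 measured genes of IL6-JAK-STAT3 signalling, 17 fell and 1 rose (18 and 3 adjusted over the list alone; 10 and 7 with spike-in centring; median -0.19, or -0.01 so centred), with camera Benjamini-Hochberg adjusted p = 7.73e-06 and adjusted p = 0.0373 with an estimated correlation. The members that fell most were FOS, IRF1 (2.78-fold), CEBPB (2.04-fold) and SOCS1 (1.81-fold), of which IRF1 is also in the interferon and NF-kB lists, FOS in the immediate early and RAS-MAPK lists and CEBPB in the stress response list. The IL6 receptor gene IL6R differed by -0.08 (95% interval -0.21 to 0.06) and STAT3 by 0.00 (95% interval -0.12 to 0.13), with limma Benjamini-Hochberg adjusted p = 0.415 and 0.977. IL6ST, the shared signalling subunit gp130, fell by 0.53 (SE 0.06; limma, Benjamini-Hochberg adjusted p = 3.00e-04). Of 10 reported CPEB3 target mRNAs, EGFR was the 1 past the threshold, lower (the same adjusted over the list alone; 1 lower and 3 higher with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.796, the median of 0.01 and mean of -0.03 differing in sign). EGFR fell by 0.60 (limma, Benjamini-Hochberg adjusted p = 3.62e-04), but of its 9 probe sets 2 were lower past the threshold and 1 higher, and with their mean the difference was -0.12 and the call was lost (limma, Benjamini-Hochberg adjusted p = 0.089). Among the other targets, GRIA1 (1.99 against 1.87), GRIA2 (1.27 against 1.22) and GRIN2A (3.66 against 3.68) lay below the median probe set in both groups. Their lack of change therefore says little. The arrays measure mRNA levels, so an effect of CPEB3 on the translation of these targets was not measured.

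The CPEB family and cytoplasmic polyadenylation list had 10 of 25 members lower and 0 higher (the same adjusted over the list alone; 5 and 4 with spike-in centring), with a median of -0.06 that turned to 0.12 with spike-in centring. Its camera Benjamini-Hochberg adjusted p was 0.00399, a call lost without dim genes and with an estimated correlation (adjusted p = 0.0832 with an estimated correlation). CPEB2 was 2.38-fold lower at 1 of its 3 probe sets, CPEB4 1.41-fold lower and the deadenylation regulators TOB2 1.72-fold and TOB1 1.52-fold lower, while CPEB1 differed by 0.23 (limma, Benjamini-Hochberg adjusted p = 0.0889) and passed the threshold with spike-in centring. Macrophage-directed cytokines fell in 16 of 45 members and rose in 3 (18 and 4 adjusted over the list alone; 12 and 10 with spike-in centring), with a median of -0.06 that turned to 0.12 with spike-in centring (camera, Benjamini-Hochberg adjusted p = 3.29e-04, adjusted p = 0.0942 with an estimated correlation). CXCL11 fell by 2.59 on the log2 scale, and CXCL10 was 5.37-fold lower and IL15 4.96-fold. CXCL10 and CXCL11 are also in the interferon list, and the CXCL11 probe set was dim in both groups (1.28 against 3.87). The camera call at the preset correlation was kept when interferon genes were left out of the list.

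Epithelial junction genes rose in 13 of 42 members and fell in 5 (the same adjusted over the list alone; 20 and 3 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.173). The epithelial cadherin CDH1 differed by -0.01 (95% interval -0.16 to 0.14), CDS1 rose 1.55-fold and the epithelial transcription factor ELF3 fell 2.04-fold. Mesenchymal genes fell in 13 of 50 members and rose in 2 (14 and 3 adjusted over the list alone; 5 and 22 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.258, or 0.0438 without dim genes), the median (0.03) and mean (-0.07) differing in sign. LOXL2, a collagen cross-linking enzyme, was 1.93-fold lower, SNAI2 1.89-fold and VIM, an intermediate filament protein, 1.35-fold (-0.17 and not past the threshold with the mean of its probe sets), whereas CDH2 (0.23) and SNAI1 (-0.25) had limma Benjamini-Hochberg adjusted p = 0.0813 and 0.055. CDH2 passed the threshold with the mean of its probe sets and with spike-in centring, and SNAI1 with median centring, repeated quantile normalization and array weights. TGF-beta/SMAD targets fell in 11 of 30 and rose in 5 (13 and 5 adjusted over the list alone; 7 and 10 with spike-in centring; median -0.15, or 0.03 so centred), and the camera call (Benjamini-Hochberg adjusted p = 0.0182) was lost on ranks, without dim genes and with an estimated correlation (adjusted p = 0.0899 with an estimated correlation). YAP/TEAD targets fell in 10 of 25 and rose in 0 (the same adjusted over the list alone; 8 and 7 with spike-in centring; median -0.08, or 0.10 so centred), and the camera call (Benjamini-Hochberg adjusted p = 0.00179) was also lost (adjusted p = 0.0889 with an estimated correlation). CCN2, in both lists, was 3.22-fold lower.

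Wnt targets had 6 of 35 members higher and 6 lower (7 and 8 adjusted over the list alone; 16 and 3 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.943), the median (0.02) and mean (-0.02) differing in sign. AXIN2, a feedback inhibitor of the pathway, rose 1.44-fold at 1 of its 4 probe sets, and PLAUR, the urokinase receptor, fell 3.48-fold. Intestinal differentiation genes had 4 of 40 higher and 4 lower (the same adjusted over the list alone; 21 and 3 with spike-in centring; camera, Benjamini-Hochberg adjusted p = 0.172, with the direction up). Without dim genes the list was called in the other direction, with a mean difference of -0.52 (camera, Benjamini-Hochberg adjusted p = 0.0438). That call rests on the brightest members alone, of which KLF4 (-1.99), GATA6 (-0.68), KLF5 (-0.45) and CA2 (-0.24) fell. CDX1 (0.12) and SPDEF (0.09) did not pass. In the full list, KRT20, an enterocyte keratin, was 1.83-fold higher. Cholesterol synthesis genes rose in 11 of 25 and fell in 4 (12 and 5 adjusted over the list alone; 16 and 1 with spike-in centring; median 0.17, or 0.35 so centred). The camera call (Benjamini-Hochberg adjusted p = 0.0284) was lost with an estimated correlation (adjusted p = 0.1 with an estimated correlation), with spike-in centring and with the other choices of probe set. TM7SF2, a sterol reductase, rose 1.73-fold.

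The size of several of these log2 differences depended on which probe sets stood for the gene or on the scaling; the values given here kept their direction and call. With the mean of all probe sets of a gene, CPEB2 was -0.40 in place of -1.25, SOCS1 -0.25 in place of -0.86, LOXL2 -0.32 in place of -0.95, TOB2 -0.42 in place of -0.78, ATF3 -0.92 in place of -1.95 and PFKFB4 -1.01 in place of -1.79. AURKB became -0.54, MKI67 -0.44, IL6ST -0.32, CDS1 0.29, AXIN2 0.17, NDUFA2 0.40 and CXCL11 -1.70 in the same way. Without probe sets that can match several transcripts, CXCL11 was -0.81, PLAUR -0.70, ATF3 -0.83 and GADD45B -0.52. CPEB4 was -0.93 at its most variable probe set. With spike-in centring, IL6ST was -0.35, VIM -0.26 and CPEB4 -0.31.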

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

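The tests of the CPEB3 probe sets, the leukocyte list, the interferon genes and the spike-in scaling were chosen after the results were seen. The tests against matched random lists and the other splits of the arrays were written before their own outcomes were seen. The matched test was written for the fall of the hypoxia and glycolysis list and the rise of the oxidative phosphorylation list. Its choice of lists therefore followed the list results.

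Signals outside the comparison of named genes were examined too. The 18 hybridization spike-in probe sets had a mean log2 intensity of 9.57 in the arrays labelled CPEB3 and 9.75 in those labelled NC, a difference of -0.18 (-0.179). The 24 poly-A spike-in probe sets differed by -0.23 (-0.229). Exact permutation tests gave p = 0.1 for both, the smallest p that 3 against 3 arrays allow. The 3' minus 5' log2 difference, a sign of RNA integrity and labelling, was 3.40 against 3.24 for ACTB and 0.07 against -0.01 for GAPDH (exact permutation p = 0.2 for both). Among the 11721 probe sets unnamed here, 872 (7.44%) passed limma's test, 508 higher and 364 lower, against 14.5% of all probe sets. At 2-fold or more, 7 of the unnamed ones were higher and 32 lower.

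With the values as deposited, CPEB3 mRNA was not higher past the threshold at any of its 4 probe sets where the labels say it was overexpressed; with spike-in centring the brightest was higher by 0.228 (limma, Benjamini-Hochberg adjusted p = 0.0432, against 0.391 to 0.935 under the other alternatives that use it). A construct outside the probed sequence explains no fall, and the most variable probe set differed by -1.44 with an SE of 0.12, which argues against that as the whole account, although this probe set is dim. For the lack of a rise it stays open, because the highest of the 4 differences was 0.05 as deposited and probe positions were not analysed here. Exchanged group labels cannot be told apart from a real fall of the endogenous mRNA: 3 of the 4 probe sets were lower in the arrays labelled CPEB3, and the brightest was not. A true effect of CPEB3 on its own mRNA was not tested.

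Interferon genes fell together in the arrays labelled CPEB3. Leukocytes among the NC cells are argued against by a median difference of 0.067 over 27 leukocyte markers, with PTPRC at 1.62 against 1.48, LYZ at 2.55 against 2.50 and TYROBP at 3.36 against 3.31; 3 of the 27 lay above the median gene in the NC arrays and 0 are in another list. Centring on the spike-ins adds 0.179 to the difference of every gene, which leaves a median of -2.157. A scaling difference of the size the spike-ins show is therefore too small to account for the fall. This follows from the size of the shift and is not a separate test. Interferon made by the NC cells stays open as a candidate explanation, since IFNB1, IFNL1 and IFNL2 had a median of -2.25. IFNB1 and IFNL1 are themselves in the interferon list and IFNL2 is among the 12 largest falls, so this median is not separate evidence. It cannot tell a cause of the response from a part of it. Whether CPEB3 or the way the constructs were delivered set the difference was not tested, because each group has 1 kind of transfection.

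In the hypoxia and glycolysis list 34 of 42 members fell, while in the oxidative phosphorylation list 31 of 46 rose. The camera call of the oxidative phosphorylation list was lost with an estimated correlation (adjusted p = 0.0808). Centring on the spike-ins, which adds 0.179 to every gene, left the hypoxia median at -0.464 and moved the oxidative phosphorylation median to 0.42. A scaling difference of that size is too small to account for the hypoxia fall. Other forms of scaling were not tested here. A trend with expression level and gene length is argued against for both lists: 10000 matched random lists had a median of 0.006 (range -0.146 to 0.145) against -0.64, and 0.066 (range -0.095 to 0.189) against 0.24. Culture density or medium at harvest may differ between the groups and stays open, as does an effect of CPEB3; neither was tested.

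The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with the most genes changed (4616), the most changed at least 2-fold (191) and the most lists (14). The highest counts of the other splits were 0 genes by limma, 0 genes at least 2-fold and 9 lists. At an unadjusted limma p under 0.05 their highest count was 809 genes, against 6976 in the real split. Each of these splits mixes both groups, so the group difference itself widens the spread within its sets of 3. Few gene calls were therefore built in, and the called lists can still carry part of the real difference. The other splits thus give no measure of chance for the counts of genes or lists.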

How the results depend on the processing

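Spike-in centring and leaving interferon genes out of the other lists were chosen after the data were seen. Of 114 named genes, values kept direction and side of the threshold in 1839 cases and lost the threshold in 30. They gained it in 11 and reversed in 8. For the 26 lists the numbers were 520, 15, 8 and 1. A change of direction where neither value passed the threshold was counted as kept, for genes and for lists. Every probe set on its own gave 7891 changed, 3597 higher, 4294 lower and 372 at least 2-fold; a threshold of 0.01 gave 2603, 1083 and 1520, by construction. Spike-in centring gave 8805 changed, 7767 higher, 1038 lower and CPEB3 at 0.228. It shifts the differences of all genes by 0.179, but each array gets its own constant, so the estimated spread changes too. PSMB9 fell less (-3.81 in place of -3.99), yet its limma Benjamini-Hochberg adjusted p went from 2.16e-09 to 5.95e-15. The share of each effect in these counts was not separated. Camera with an estimated correlation called 7 lists in place of 14. CPEB3 became -0.498 with the mean of its probe sets and -1.444 with the most variable one, because these differ from the brightest. Also reversed were SC5D (-0.086), DCN (-0.099) and H2AZ2 (0.29) without probe sets that can match several transcripts. H2AZ2 (0.054) and ITGAM (-0.095) reversed with the mean, and ITGAM (-0.513) with the most variable probe set. Why these probe sets differ was not tested. The intestinal list reversed (-0.523) without dim genes, where its brightest members remained and KLF4 (-1.99) fell most.

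Leaving out 1 array gave 3373 to 4354 genes changed, 1512 to 1942 higher, 1861 to 2412 lower, 185 to 205 at least 2-fold, 14 to 15 lists and CPEB3 at 0.011 to 0.079. Some results gained a call without 1 array (limma or camera, Benjamini-Hochberg): CPEB1 without CPEB3 replicate 1 (0.302, adjusted p = 0.0424), CDH2 without NC replicate 2 (0.307, adjusted p = 0.0338), SNAI1 without NC replicate 3 (-0.299, adjusted p = 0.0469), the intestinal list without CPEB3 replicate 3 (adjusted p = 0.0411) and heat shock proteins without NC replicate 3 (adjusted p = 0.0496). Others lost theirs: CDC25A without CPEB3 replicate 1 (adjusted p = 0.0619), HSPB1 without NC replicate 2 (0.0503), CORO1A without CPEB3 replicate 2 or 3 or NC replicate 2 (0.0648 to 0.0694), ESAM without CPEB3 replicate 1 or 3 or NC replicate 1 or 2 (0.0623 to 0.0928), and ENG without any array but NC replicate 3 (0.0567 to 0.111). With all arrays, SNAI1 also passed with median centring (0.0425), quantile normalization once more (0.0414) and array weights (0.0406), CDH2 with the mean of its probe sets (0.0214) and spike-in centring (0.00482), and CPEB1 with spike-in centring (0.00519). Lists that gained a call with all arrays were mesenchymal genes without dim genes (0.0438) and by fry (0.00383), the intestinal list without dim genes (0.0438, in the reversed direction), heat shock proteins with the mean of probe sets (0.0457), on ranks (0.0467) and by fry (0.0129), and histone genes by fry (0.0138). Fry tests a list against no change and camera tests it against the other genes, so the fry calls answer a different question. With the replicate block, 4262 genes changed. Deviations of same-numbered arrays correlated at 0.00, -0.02 and 0.12. Arrays of different numbers were not compared in this way, so whether the numbers pair the samples stays open. With the block the cholesterol list lost its call and SNAI1 gained one. No signal over background was used, so dim genes are limited by an unknown floor.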

Other observations

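The gene groups below were chosen after their values were seen, so their tests are not independent evidence. The copy number test was written before its own outcome was seen.

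Genes of MHC class I antigen presentation were lower in the arrays labelled CPEB3. Of 16 measured, 13 fell, 0 rose and 3 did not pass (camera, Benjamini-Hochberg adjusted p over 3 such lists = 8.81e-15, adjusted p = 0.00319 with an estimated correlation). The median was -1.06, and -0.88 with spike-in centring, after which 11 were lower and 1 higher. The peptide transporter subunits TAP1 and TAP2 were 5.02-fold and 3.50-fold lower, the class I transactivator NLRC5 3.66-fold, and HLA-B 2.74-fold. HLA genes are closely related, so their probe sets can read one another, and 6 of the 16 are also in the interferon list. PSMB8 (-0.51), PSMB10 (0.14) and ERAP2 (-0.02) did not pass, but PSMB10 was higher with spike-in centring (0.32, limma, Benjamini-Hochberg adjusted p = 0.0104). CD274, which encodes the checkpoint ligand PD-L1, was 4.18-fold lower, the dendritic cell protein gene LAMP3 7.88-fold, the chemokine receptor gene CXCR4 5.72-fold and CCL5 3.56-fold.

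Metallothioneins, which bind zinc and copper, were lower in 7 of 8 measured genes (median -0.37, -0.19 with spike-in centring, after which 3 were lower and 1 higher; camera, Benjamini-Hochberg adjusted p = 3.85e-05, adjusted p = 0.0182 with an estimated correlation). MT1F was 1.43-fold lower and MT1X 1.42-fold, and their sequences are close enough for shared signal. Genes of mitochondrial fatty acid oxidation were higher in 6 of 19 and lower in 1 (16 and 0 with spike-in centring; median 0.14, 0.32 so centred; camera, Benjamini-Hochberg adjusted p = 2.74e-04, adjusted p = 0.0473 with an estimated correlation). DECR1 and ACADSB were 1.66-fold and 1.65-fold higher, and ACADVL 1.19-fold lower, but -0.07 and not past the threshold with spike-in centring. The oxidoreductase gene DHRS2 was 6.08-fold lower, IGFBP3 3.92-fold lower and the miR-200c host transcript MIR200CHG 2.08-fold higher.

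The many small changes may come from a copy number difference between the cell populations. Differences of genes 10 places apart on a chromosome had a Spearman correlation of 0.003 over 9837 genes, which argues against that for large segments. Adjacent genes gave 0.046, above the 95% range of permuted orders of -0.018 to 0.022. The hybridization spike-ins, which do not come from the cells, also differed between the groups (-0.18). The labels give no day or batch, so a technical difference aligned with the groups cannot be told apart from one between the cells.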
